A study of Mus musculus with 8 samples.

How the data were processed

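Pancreatic lymph nodes of 8 Deaf1 knockout mice on the BALB/c background were profiled, each against a pool of wild-type littermates of its age, per the labels. RNA was extracted with Trizol and RNeasy columns, 1 µg of total RNA was amplified and labelled, the knockout with Cy5 and the pool with Cy3, and each pair was hybridised to an Agilent mouse array of 2 colours. No array had the dyes swapped and none held a wild-type mouse against the pool, so dye bias and the spread of the controls are not in any test below. The wild-type channels of 2 arrays of the same age correlated across genes at 0.998 to 0.999 at 12 and 30 weeks and at 0.984 at 4 weeks. The 4-week value does not show a shared pool: wild-type channels of 12 and 30 weeks reached 0.984 with each other. The 2 knockout channels of 4 weeks correlated at 0.983. That the arrays of an age share their pool is an assumption. Under it an age is represented by a single pool, and differences between ages are differences between pools as well.

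The deposited scanner files hold, per the file headers, mean spot and median local background brightness (intensity) and processed signals (intensity) written by Agilent Feature Extraction 9.5.3.1 for the 2 arrays of 4 weeks and 10.2.1.3 for the other 6. They also hold, per the file headers, a log ratio of red over green processed signal on the log10 scale, and quality flags. The deposited series matrix gave, by comparison with the scanner values (Pearson's r of at least 0.99998 on each array), the log2 of red over green processed signal made by the authors, with red as knockout. It was not centred, its medians per array being −0.10, −0.21, −0.12, −0.05, −0.09, −0.12, 0.15 and −0.13 in order of age and replicate. The software behind it is unknown. Slide, scanner and software were read from the files: slide 1 held the 4-week arrays, on a scanner of its own, slide 2 the 3 arrays of 12 weeks and replicate 1 of 30 weeks, and slide 3 replicates 2 and 3 of 30 weeks.

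Each array held 45018 spots, of which 43379 were not controls, for 41174 probes. No spot was saturated. Well above background were 37.2% to 62.6% of probes in Cy3 and 46.8% to 71.4% in Cy5, and the spike-in slopes ran from 0.922 to 0.961. With limma 3.58.1 in R 4.3.3, mean signals were corrected with normexp (offset 50), loess-normalised within arrays with control spots at weight 0, and spots of a probe were averaged without flagged outliers. A probe was kept if well above background in the same channel on all arrays of at least 1 age, which left 27463 probes, and each gene was represented by its brightest probe, which left 18382 genes. For these, 27 values by gene and array were missing, and each gene had at least 6. Probe names came from the accession in the files through a RefSeq annotation (GRCm38.p6, used for names only) for 25108 probes, through a current symbol for 5875 and through a unique synonym for 2213, and 7978 kept the file's name. For 4276 probes the later files give another accession than the 4-week files, with a different symbol for 90. Coordinates are those of the 4-week files (mm8).

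A limma model with 1 mean per age was fitted to all 8 arrays (5 residual and 3.39 prior degrees of freedom). Tested against 0, two-sided, were 7 contrasts: the ratio at 4, 12 and 30 weeks, their mean, and the differences of 12 minus 4, 30 minus 12 and 30 minus 4 weeks. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast are called. Standard errors are those of the moderated fit. A dye bias of a probe that is equal on all arrays cancels in the differences between ages but not in the other contrasts. Where a gene was not well above background on any array of a group, its fold is a bound, the brighter group's mean over the dimmer group's mean of, per array, the higher of its own signal and the lowest signal among probes well above background. Differences between ages are fitted values, not bounds, for Dct, Gcnt1, Adam33, Thumpd1, Alb and Lor, which were not well above background in 1 channel at 4 weeks (Dct also at 12 and 30 weeks, Alb also at 30 weeks), and for Cfap74, which was so in both channels at 12 weeks and in 1 at 30 weeks.

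Named in each contrast are Deaf1, Aire and Eif4g3, the 10 called genes with the largest rise and the 10 with the largest fall whose sign is equal on every array of the contrast (for a difference between ages, with no overlap between the 2 ages), leaving out rows named only by an accession or clone, and, from each gene list with a shift, up to 4 members with the smallest p in its direction. Cxcl10 at 30 weeks, the sex-linked genes and the genes of the observations section that fall outside this rule were chosen after their values were seen. Results of 2 genes that this rule would name are not reported here. The 29 lists cover pancreatic acinar and islet cells, liver, gut, neural, skin and reproductive or endocrine antigens, fibroblastic reticular cells, lymphatic and blood endothelium, B cells, germinal centre, plasma cells, T cells, regulatory T cells, cytotoxic and natural killer cells, dendritic cells, macrophages, neutrophils, erythroid cells, fat cells, skeletal muscle, cell cycle, interferon response, inflammatory cytokines and chemokines, translation initiation, class II antigen presentation, immediate-early and heat-shock genes and sex-linked genes. Lists with at least 5 measured genes, 28 of them, were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over the lists of a contrast), and again with an estimated correlation. Members passing over all genes and adjusted over the list alone were counted. Enrichment near Deaf1 used Fisher's exact test on the 18232 tested genes with a position.

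The samples, tests, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were no background correction, the scanner's log ratio, median centring alone, the series matrix values, scaling between arrays, no filter or a stricter filter on dim probes, the mean of all probes of a gene that passed the filter, a trended robust prior, array weights, a fit on the ages compared alone, a replicate block, slide as a fixed or random block, leaving out each array, an absolute log2 ratio over 1, an estimated correlation for lists and other windows around Deaf1. Added after the data were seen were a correction for probe GC content, alone and with the replicate block, the mean of 12 and 30 weeks only, and slide 2 alone. On simulated data with 200 changed genes the fit recovered 44.8% (4 weeks), 64.2% (12 weeks), 73.1% (30 weeks) and 94.0% (mean) of changes of 0.5 and 95.5%, 98.5%, 97.0% and 100% of changes of 1 on the log2 scale. For differences between ages it recovered 16.4% to 28.4% of changes of 0.5 and 86.6% to 98.5% of changes of 1. False calls made up 2.03% to 7.61%, and a simulated list shift was found in all 7 contrasts with 0 other lists called. The simulated values were drawn independently for each gene and array. They therefore do not show how the tests behave with correlated genes, a dye or GC trend or a shared pool. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Per-sample data columns left unused numbered 0.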

Results

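Messenger RNA of the pancreatic lymph node, the node that drains the pancreas, was measured in BALB/c mice lacking Deaf1, a transcription factor, on 8 microarrays of 2 colours. Each array set 1 knockout mouse (Cy5) against a pool of wild-type littermates of the same age (Cy3). There were 2 arrays at 4 weeks, with a pool of 2 mice, and 3 arrays each at 12 and 30 weeks, with pools of 3 mice. Each array held 41174 probes, of which 37.2% to 62.6% lay well above background in the wild-type channel and 46.8% to 71.4% in the knockout channel. The lowest shares belonged to replicate 2 of 4 weeks. After a filter on dim probes 18382 genes were tested, and the small number of arrays limits the precision. Values are log2 ratios of knockout over wild type, given with the standard error of the fit unless an SD is named.

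Genes of the sex chromosomes differed between the ages. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d lay well above background in the wild-type channel of all 3 arrays at 12 weeks and in the knockout channel of replicates 1 and 3. At 4 and 30 weeks they were not well above background in either channel, apart from Eif2s3y in the wild-type channel of 1 array at 30 weeks. Xist, the RNA that silences an X chromosome in females, had a log2 level of 7.55 to 7.71 in the 12-week pool and 12.42 to 13.12 in the pools of the other ages. In replicate 2 of 12 weeks the ratio of Xist was 5.32 and those of Ddx3y and Eif2s3y were −3.89 and −4.86. The labels give no sex. In these genes the mouse of that array differed from its pool, and 12 weeks from the other ages, in the way in which the sexes differ.

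Deaf1 itself, the targeted gene, was measured by a probe on chromosome 7 at 141152927 to 141152986 (mm8). Its log2 ratio was −0.17 ± 0.07 at 4 weeks (adjusted p = 0.127, n = 2), 0.34 ± 0.06 at 12 weeks (adjusted p = 0.0344, n = 3) and 0.10 ± 0.06 at 30 weeks (adjusted p = 0.225, n = 3). A second probe, at 141166259 to 141172439, had means of −0.19 (SD 0.14) at 4 weeks, 0.15 (SD 0.03) at 12 weeks and 0.58 (SD 2.19) at 30 weeks. Its values at 30 weeks were −0.74, 3.11 and −0.62 in replicates 1, 2 and 3, signs that the pancreatic acinar genes described below shared on these arrays. The last Deaf1 probe was not well above background on any array. The call at 12 weeks was lost with several other settings, among them the scanner's own log ratio (0.41) and the mean of the 2 Deaf1 probes that passed the filter (0.24). Which part of the gene was deleted is not stated in the labels, so these probes do not check the genotype.

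Eif4g3, which encodes a scaffold protein of translation initiation, was lower in knockout nodes at every age. It fell by 0.97 ± 0.09 at 4 weeks (adjusted p = 0.000521, n = 2), 1.35 ± 0.07 at 12 weeks (adjusted p = 0.000384, n = 3) and 1.49 ± 0.07 at 30 weeks (adjusted p = 0.000339, n = 3), and its ratio was below 0 on 8 of 8 arrays. The probe lies on chromosome 4 at 137478284 to 137478343. Another Eif4g3 probe gave −1.07 (SD 0.09), −1.55 (SD 0.17) and −1.81 (SD 0.12) at these ages. Aire, the regulator of self-antigen expression in thymus and lymph node, had a ratio of −0.25 ± 0.13 at 4 weeks (adjusted p = 0.193), fell by 0.51 ± 0.10 at 12 weeks (adjusted p = 0.0472) and rose by 0.38 ± 0.10 at 30 weeks (adjusted p = 0.0203). The call of Aire at 12 weeks was lost in each of the 8 fits that left out 1 array and kept in 5 of the 23 alternative settings that include these fits, and the ratio turned to 0.03 when arrays were only centred on their median. Under that centring the median of all genes at 12 weeks was 0.41, above that of Aire.

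**Figure D1:**
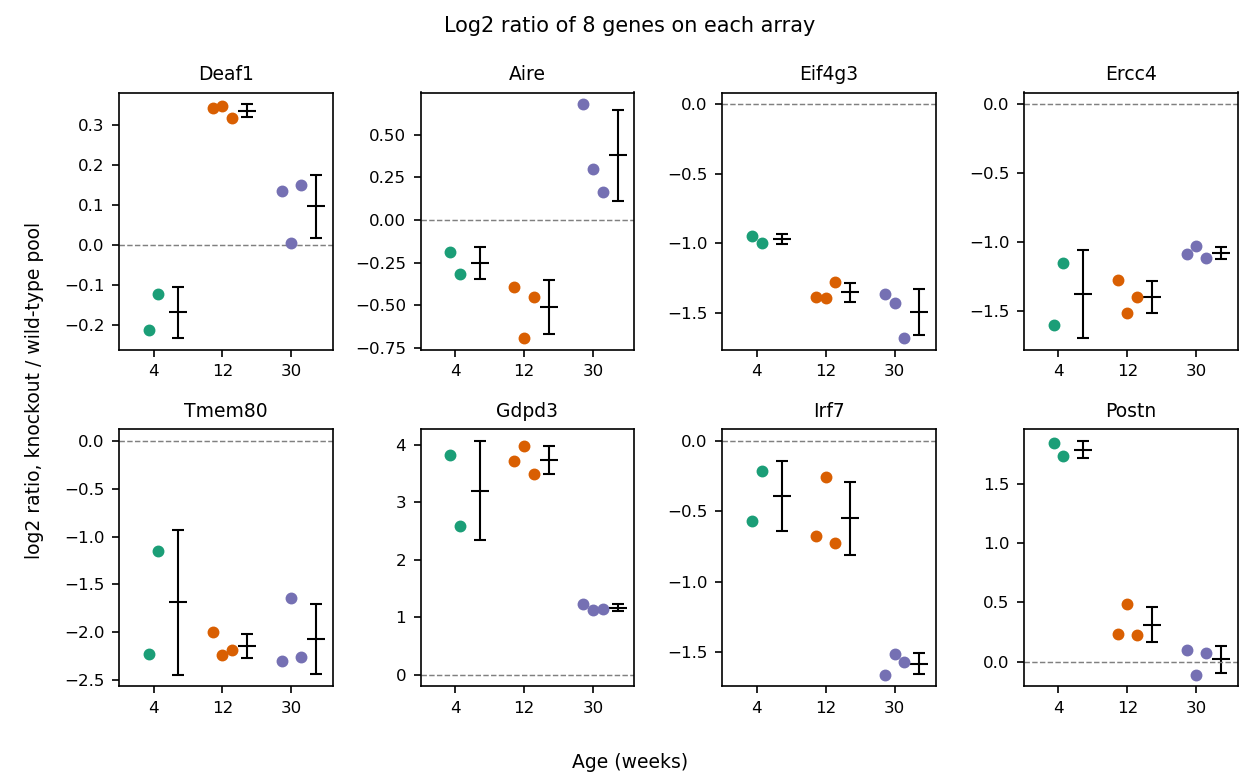
Log2 ratio of knockout over wild-type pool (vertical axes) at 4, 12 and 30 weeks (horizontal axes) for 8 genes, with a coloured dot per array (n = 2, 3 and 3) and the mean ± SD in black. Eif4g3, Ercc4 and Tmem80 lie below 0 and Gdpd3 above 0 on all 8 arrays, and Irf7 is lowest at 30 weeks (mean −1.58).

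The mean of the 3 ages, each with equal weight, was tested against 0, so a gene changed mainly at 1 age can pass. Besides Eif4g3 (−1.27 ± 0.05, adjusted p = 2.57e-05), the largest falls were in Tmem80 (−1.97 ± 0.12, adjusted p = 0.00024), whose probe on chromosome 7 at 141187810 to 141187869 lies next to that of Deaf1, and in Ercc4 (−1.28 ± 0.06, adjusted p = 5.44e-05), which encodes a subunit of a DNA repair nuclease. Gdpd3, an enzyme of the lysophospholipase D family on chromosome 7 at 126562154 to 126562327, rose by 2.70 ± 0.12 (adjusted p = 5.44e-05). Other falls were in Adipoq, the fat-cell hormone adiponectin (−1.12 ± 0.24), the immunoglobulin light-chain segment Igkv19-93 (−1.10 ± 0.08) and another kappa light-chain segment (−0.94 ± 0.15), the RNA-binding protein Hnrnpc (−0.92 ± 0.09), Ypel5 (−0.88 ± 0.08), Cpxm1 (−0.87 ± 0.09) and Irf7, a transcription factor of the interferon response (−0.84 ± 0.07). Further rises were in the paired immunoglobulin-like receptor Pira2 (1.05 ± 0.14), Luc7l2 (0.99 ± 0.08), Znf41-ps (0.97 ± 0.09), the immunoglobulin heavy chain Igh (0.95 ± 0.17), the chemokine Cxcl10 (0.92 ± 0.12), Enpp4 (0.87 ± 0.06), the actin-binding Tmsb4x (0.87 ± 0.10), Smchd1 (0.86 ± 0.06) and the RNA helicase Dhx9 (0.85 ± 0.08). For Igh, 3 of 6 other probes had the same sign, and for Ypel5 0 of 1. Deaf1 (0.09 ± 0.04, adjusted p = 0.0819) and Aire (−0.13 ± 0.06, adjusted p = 0.141) did not pass.

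Over the 8 arrays limma called 8109 genes in this mean, 4675 higher and 3434 lower, but only 17 with an absolute log2 ratio over 1. The median size of the called ratios was 0.27. None of the 28 lists tested shifted, the lowest adjusted p being 0.124. Without replicate 1 of 4 weeks 5114 genes passed, and of the 20 named calls 0 were lost when 1 array was left out. Between ages, shared calls exceeded what independent calls would give: 12 and 30 weeks had 180 rises and 177 falls in common against 47.1 and 46.3, and 9 opposite calls against 94.0. At 4 and 30 weeks 1210 rises and 472 falls were shared against 581 and 249, and 462 calls were opposite against 797, while 4 and 12 weeks shared 114 rises and 81 falls against 34.9 and 18.6, with 25 opposite against 55.4. At all 3 ages 89 genes rose and 58 fell. The pools differ between ages, but every array has the knockout in Cy5, so a dye bias of a probe enters these overlaps. A trend of the ratios with probe GC content, seen on all 8 arrays, enters them too. All ages also share 1 estimate of the spread per gene, so calls at different ages are not independent tests.

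At 4 weeks, the youngest age, the largest fitted rise was in Gcnt1, a glycosyltransferase that branches O-linked sugars. It was not well above background in the pool, and its level was at least 13.5-fold higher in the knockouts (fitted log2 ratio 3.75 ± 0.66, adjusted p = 0.00589, n = 2, with 5.07 and 2.43 in replicates 1 and 2). Gdpd3 rose by 3.20 ± 0.24, Erdr1 by 2.74 ± 0.33, the protease inhibitor Slpi by 2.61 ± 0.50, Eaf2 by 2.25 ± 0.38, Rpgrip1 by 1.86 ± 0.27, the matrix protein Postn by 1.79 ± 0.09 and Pira2 by 1.77 ± 0.27. The metalloprotease Adam33 was at least 4.43-fold and Thumpd1 at least 5.39-fold higher, although the 1 other probe of Thumpd1 had the opposite sign. Dct, a melanin-synthesis enzyme of pigment cells, was at least 9.73-fold lower over both arrays (fitted log2 ratio −3.28 ± 0.50, with −4.71 and −1.85 in replicates 1 and 2), and was not well above background in either knockout. Also lower were Cd207 (−2.09 ± 0.57), the langerin of skin-derived dendritic cells, the T-cell receptor chain Tcra (−1.91 ± 0.41), the secretory-granule protein Scg5 (−1.80 ± 0.27), Tmem80 (−1.69 ± 0.24), Dok2 (−1.63 ± 0.29), Lrmda (−1.62 ± 0.47) and the fat-cell genes Plin4 (−1.63 ± 0.47), Cidec (−1.55 ± 0.45) and Gpd1 (−1.42 ± 0.36). Of the 25 named calls at this age 19 were lost in at least 1 of the 8 fits that left out 1 array, Plin4 in 5 and Lrmda and Cidec in 4. Without replicate 1 the ratios were 1.57 for Thumpd1, 1.17 for Pira2, −1.36 for Cd207 and −0.41 for Lrmda. Without replicate 2 that of Tcra was −0.93.

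Of 14 measured genes of cytotoxic and natural killer cells, 6 fell at 4 weeks, 0 rose and 8 did not pass (6 fell adjusted over the list alone), with a list median of −0.33 that turned to 0.23 when arrays were only centred on their median. It was −0.085 without replicate 1 and −0.53 without replicate 2. Examples were the granzyme Gzma (−0.78 ± 0.13), the receptor Ncr1 (−0.54 ± 0.12), the transcription factor Tbx21 (−0.53 ± 0.13) and the chemokine Ccl5 (−0.72 ± 0.20), of which Tbx21 and Ccl5 turned to 0.38 and 0.21 in the same way. Under that centring the median of all genes at 4 weeks was 0.49, above the list median, Tbx21 and Ccl5. The list passed the preset-correlation test (adjusted p = 0.0464) but not with an estimated correlation (adjusted p = 0.90), and the call was lost in 3 of the 8 fits that left out 1 array. The other 27 lists did not pass at this age. limma called 4168 genes, 2814 higher and 1354 lower, 257 of them with an absolute log2 ratio over 1. The count fell to 494 without replicate 1, and the 2 arrays shared a slide, a scanner and a software version that no other age used.

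At 12 weeks fewer genes passed. Gdpd3 rose by 3.73 ± 0.19 (adjusted p = 0.000384, n = 3), Thumpd1 by 1.76 ± 0.32, H60, a stress ligand of the killer-cell receptor NKG2D, by 1.20 ± 0.19 and Cxcl10, an interferon-induced chemokine, by 1.03 ± 0.19. Rn18s, a ribosomal RNA, and Lars2, a mitochondrial tRNA synthetase, rose by 1.17 ± 0.20 and 1.10 ± 0.14. Rpgrip1 (1.10 ± 0.22), Wfdc17 (0.92 ± 0.16), Adam33 (0.89 ± 0.10) and the cell-cycle gene Ccnd1 (0.86 ± 0.07) were higher too. Tmem80 fell by 2.14 ± 0.19, Timp4, an inhibitor of matrix proteases, by 1.60 ± 0.27, the integrin Itga8 by 1.59 ± 0.15, Cpxm2 by 1.41 ± 0.12, Ercc4 by 1.40 ± 0.09, Igkv19-93 by 1.25 ± 0.12 and the collagen Col8a2 by 1.15 ± 0.14. The granule proteins of myeloid cells Mpo and Prg2 fell by 1.21 ± 0.25 and 1.16 ± 0.09. Of the 22 named calls at this age 13 were lost in at least 1 of the 8 fits that left out 1 array, those of Cxcl10 and Rpgrip1 in 7, of Rn18s, Wfdc17 and Mpo in 6, of Thumpd1 and Timp4 in 5 and of H60 and Deaf1 in 4.

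Among 12 measured fat-cell genes none passed over all genes and 8 were lower adjusted over the list alone. The list median was −0.95, with ratios of −1.44 ± 0.39 for Adipoq, −1.21 ± 0.36 for Cidec, −1.10 ± 0.30 for the lipid-droplet protein Plin1 and −1.10 ± 0.29 for Thrsp. The list medians were −1.45, −1.25 and 0.0046 in replicates 1, 2 and 3. Without replicate 1 Adipoq, Cidec and Thrsp had −0.87, −0.79 and −0.68. Cell-cycle genes had a median of 0.29. None of the 20 passed over all genes, and 11 were higher adjusted over the list alone. Ratios were 0.38 ± 0.08 for the replication helicase subunits Mcm2 and Mcm4, 0.39 ± 0.09 for the mitotic kinase Plk1 and 0.40 ± 0.10 for Cdk1. Both lists passed the preset-correlation test (adjusted p = 5.16e-05 and 1.70e-06), and neither passed with an estimated correlation (adjusted p = 0.841 for both). The other 26 lists did not pass at 12 weeks. limma called 480 genes, 228 higher and 252 lower, 26 of them with an absolute log2 ratio over 1. This count hung on single arrays: it was 18, 1862 and 131 without replicates 1, 2 and 3 of 12 weeks, 37, 229 and 27 without those of 30 weeks and 268 without either array of 4 weeks. The ratios of replicate 2, the array whose sex-linked genes differed from the pool, correlated across genes with those of replicates 1 and 3 at 0.16 and 0.07, against 0.58 between those 2.

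At 30 weeks the knockout nodes had lower levels of interferon-response genes. Of 18 measured members 13 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone, and the list median was −0.50. Irf7, whose probe on chromosome 7 at 141116085 to 141116435 lies close to that of Deaf1, fell by 1.58 ± 0.10 (adjusted p = 0.00064, n = 3). The antiviral enzymes Oas1a and Oas2 fell by 0.99 ± 0.13 and 0.79 ± 0.12, and the ubiquitin-like Isg15 by 0.66 ± 0.11, whereas Cxcl10 rose by 0.73. The list passed with a preset correlation (adjusted p = 0.000171) but not with an estimated correlation (adjusted p = 0.732). Of 11 genes of class II antigen presentation 6 fell and 5 did not pass, also adjusted over the list alone, with a median of −0.34 that turned to 0.042 when arrays were only centred on their median. They included H2-DMb2 (−1.30 ± 0.20), H2-Ob (−1.29 ± 0.32), H2-Aa (−0.72 ± 0.16) and H2-Eb1 (−0.53 ± 0.11), the last of which turned to 0.041 in the same way. Under that centring the median of all genes at 30 weeks was 0.15, above the list median and H2-Eb1. The class II list passed with a preset correlation (adjusted p = 0.0232) and not with an estimated correlation (adjusted p = 0.903). Of 15 B-cell genes 7 fell and 2 rose (median −0.32), and of 15 macrophage genes 6 fell and 2 rose (median −0.27). Neither list passed (adjusted p = 0.125 and 0.0937).

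Other falls at 30 weeks were in Tmem80 (−2.07 ± 0.19), the acute-phase gene Saa3 (−1.85 ± 0.17), the matrix protein Dpt (−1.83 ± 0.21), the splicing and RNA-binding proteins Srsf5 (−1.97 ± 0.34) and Hnrnpc (−1.74 ± 0.14), Igkv19-93 (−1.73 ± 0.12), the other kappa light-chain segment (−1.63 ± 0.24), the glucocorticoid-induced Tsc22d3 (−1.57 ± 0.30) and Ypel5 (−1.55 ± 0.12). The vesicle-traffic GTPase Rab6b rose by 1.99 ± 0.25, Rn18s by 1.60 ± 0.20, Lars2 by 1.55 ± 0.14, the choline kinase Chka by 1.40 ± 0.12, the histone methyltransferase Setd1b by 1.19 ± 0.13 and Smad7, an inhibitor of TGF-beta signalling, by 1.18 ± 0.15. Smaller rises were in Cbll1 (1.18 ± 0.16), Cab39 (1.17 ± 0.11), the taurine transporter Slc6a6 (1.17 ± 0.09) and Gdpd3 (1.17 ± 0.19). The 1 other probe of Slc6a6 had the opposite sign. Transcripts of pancreatic acinar cells, which make digestive enzymes, differed widely between the 3 arrays, with list medians of −4.09, 3.98 and −4.50 in replicates 1, 2 and 3, and the list did not pass at this age. limma called 7176 genes, 3797 higher and 3379 lower, 170 of them with an absolute log2 ratio over 1. Without replicate 1 or 3 the count was 4114 or 3929. The ratios of replicate 2 correlated across genes with those of replicates 1 and 3 at 0.38 and 0.36, against 0.88 between those 2. Of the 29 named calls 3 were lost when 1 array was left out, Aire without replicate 1 (0.23), H2-Aa without replicate 1 (−0.67) and H2-Ob without replicate 2 or 3 (−1.04 and −1.08).

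**Figure D2:**
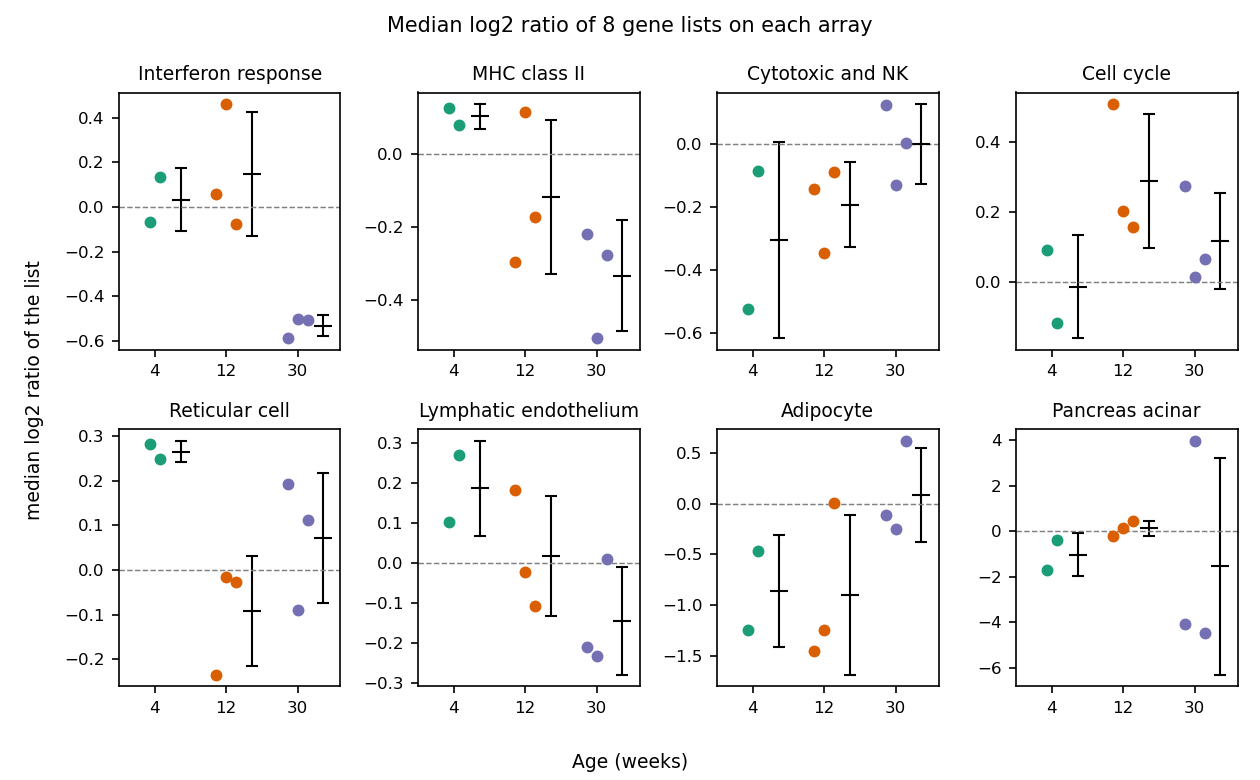
Median log2 ratio of knockout over wild-type pool (vertical axes, each panel to its own scale) at 4, 12 and 30 weeks (horizontal axes) for 8 gene lists, with a coloured dot per array (n = 2, 3 and 3) and the mean ± SD in black. The interferon-response medians of 30 weeks lie between −0.59 and −0.50, while the acinar medians of that age spread from −4.50 to 3.98.

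Whether the knockout effect differed between 12 and 4 weeks was tested next. Of 18 measured genes of fibroblastic reticular cells, the scaffold cells of the node, 6 had a lower ratio at 12 weeks and 12 did not pass (8 adjusted over the list alone), with a median difference of −0.38. This list passed with a preset correlation (adjusted p = 0.000979) but not with an estimated correlation (adjusted p = 0.673). The matrix genes Postn (−1.48 ± 0.12), Dcn (−1.19 ± 0.20) and Lum (−0.88 ± 0.15) and the receptor Pdgfra (−0.86 ± 0.19) were among the 6. Erdr1 (−2.67 ± 0.43), Adat2 (−2.18 ± 0.28), Magi1 (−1.76 ± 0.24), the lipase Lpl (−1.65 ± 0.31), Snai2 (−1.56 ± 0.32), the lymphatic receptor Lyve1 (−1.52 ± 0.27), the fatty-acid receptor Cd36 (−1.46 ± 0.18) and Ptn (−1.46 ± 0.17) were also relatively lower at 12 weeks. Relatively higher were Dct (3.21 ± 0.65), Scg5 (2.32 ± 0.35), H60 (1.76 ± 0.30), Rec114 (1.60 ± 0.34), Aqr (1.49 ± 0.18), Zbtb32 (1.37 ± 0.16), the RNA Rmrp (1.36 ± 0.15), Tatdn2 (1.3 ± 0.21), the chemokine Ccl24 (1.18 ± 0.26), Tspo2 (1.09 ± 0.18) and Deaf1 (0.51 ± 0.09, adjusted p = 0.0202). Aire (−0.26 ± 0.16) and Eif4g3 (−0.38 ± 0.12, adjusted p = 0.0884) did not pass.

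Cell-cycle genes had a median difference of 0.25 between 12 and 4 weeks, with 1 of 20 higher, 1 lower and 18 not passing (4 higher and 2 lower adjusted over the list alone). Mcm2 (0.69 ± 0.13) passed, and Cdc20 (0.72 ± 0.18), Plk1 (0.58 ± 0.15) and Aurka (0.63 ± 0.19) did not. The cell-cycle list passed with a preset correlation (adjusted p = 0.0192), but not with an estimated correlation (adjusted p = 0.872). The cell-cycle median was 0.16 without replicate 2 of 4 weeks, and its call was lost in 2 of the 8 fits that left out 1 array. Each of the 25 named calls was lost in 1 to 6 of these fits, that of Deaf1 in 3. Dct had 1.78 without replicate 1 of 4 weeks, Aire −0.17 without replicate 2 of 12 weeks and Aurka 0.41 without replicate 1 of 12 weeks. limma called 1284 genes, 253 higher and 1031 lower. The count was 1 and 627 without replicates 1 and 2 of 4 weeks, 489 without replicate 3 of 12 weeks, and 583 and 545 without replicates 1 and 3 of 30 weeks. The 2 ages lay on different slides, so that slide and age cannot be told apart, and the pool and the sex-linked genes differed with them too. Scanner, software version and the number of mice in the pool did so as well.

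Between 30 and 12 weeks the interferon-response list had the lowest adjusted p of the lists tested with the preset correlation (6.14e-10), and did not pass with an estimated correlation (adjusted p = 0.369). Of 18 members 3 were relatively lower at 30 weeks and 15 did not pass (13 lower adjusted over the list alone), with a median of −0.65: Irf7 by −1.03 ± 0.15, Oas1a by −1.09 ± 0.18 and Oas2 by −1.04 ± 0.17, while Rsad2 had −0.53 ± 0.09 (adjusted p = 0.0517). Aire was relatively higher at 30 weeks (0.89 ± 0.15, adjusted p = 0.044), a call lost in 7 of the 8 fits that left out 1 array. Each of the 21 named calls was lost in 3 to 7 of these fits. Also relatively higher were Rab6b (2.09 ± 0.36), Itga8 (1.66 ± 0.21), the nitric oxide receptor subunit Gucy1a1 (1.24 ± 0.20), the membrane protease Mmp14 (1.23 ± 0.19), Cpxm2 (1.10 ± 0.17), Ankib1 (1.04 ± 0.18), Fhl1 (1.03 ± 0.16), Zfp862-ps (1.01 ± 0.16), Slc6a6 (1.01 ± 0.13) and Cfap74 (0.93 ± 0.12). The 1 other probe of Mmp14 had the opposite sign. Gdpd3 (−2.56 ± 0.27), Saa3 (−1.87 ± 0.24), Igkv6-14 (−1.45 ± 0.16), the class I gene H2-Q9 (−1.35 ± 0.22), Tatdn2 (−1.25 ± 0.19), Adam33 (−1.24 ± 0.15) and Plac9a (−1.07 ± 0.16) were relatively lower. Deaf1 (−0.24 ± 0.08) and Eif4g3 (−0.14 ± 0.10, and −0.047 without replicate 3 of 30 weeks) did not pass.

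In 7 other lists that passed with the preset correlation between 30 and 12 weeks, 0 members passed over all genes. None of them passed with an estimated correlation (adjusted p = 0.369 for the lymphatic and plasma-cell lists, and 0.717 to 0.824 for the others). Medians were −1.72 for acinar genes (0 of 25 adjusted over the list alone), such as Amy2a5 (−2.84 ± 2.29), Pnliprp1 (−2.61 ± 2.07), Cela1 (−2.19 ± 1.81) and Pnliprp2 (−2.05 ± 1.90), and 0.98 for fat-cell genes (2 of 12 higher adjusted over the list alone), such as Plin1 (1.57 ± 0.42), Lpl (1.17 ± 0.27), Thrsp (1.09 ± 0.41) and Fabp4 (1.01 ± 0.39). Lymphatic endothelium had −0.27 (1 of 12 lower adjusted over the list alone), with Stab1 (−0.56 ± 0.18), the platelet integrin Itga2b (−0.48 ± 0.11), Stab2 (−0.35 ± 0.12) and Flt4 (−0.19 ± 0.09), and blood endothelium −0.16 (2 of 15), with Vwf (−0.73 ± 0.24), Tek (−0.54 ± 0.14), Pecam1 (−0.40 ± 0.18) and Tie1 (−0.34 ± 0.08). Plasma-cell genes had −0.17 (2 of 13), with Mzb1 (−0.67 ± 0.17), Sdf2l1 (−0.46 ± 0.16), Prdm1 (−0.42 ± 0.10) and Irf4 (−0.32 ± 0.13). Cell-cycle genes had −0.15 (3 of 20), with Top2a (−0.67 ± 0.14), Ccnb1 (−0.52 ± 0.14), Mcm5 (−0.47 ± 0.11) and Plk1 (−0.40 ± 0.13), and class II genes −0.23 (1 of 11), with H2-Ob (−1.82 ± 0.45), H2-Oa (−0.57 ± 0.26), H2-DMb2 (−0.56 ± 0.28) and H2-DMa (−0.30 ± 0.16). Left-out arrays moved several of these medians. Acinar genes had −4.58 and −0.22 without replicates 2 and 3 of 30 weeks, and blood endothelium −0.070 without replicate 2 of 30 weeks. Class II genes had −0.41 and −0.091 without replicates 1 and 2 of 12 weeks. Cell-cycle genes had −0.25 without replicate 1 of 30 weeks and −0.041 without replicate 1 of 12 weeks, and fat-cell genes 0.54 without replicate 1 of 12 weeks. Of single members, Amy2a5, Pnliprp1, Cela1 and Pnliprp2 had −6.07, −5.57, −4.79 and −4.80 without replicate 2 of 30 weeks. Amy2a5, Cela1 and Pnliprp2 had −1.18, −0.85 and −0.66 without replicate 1 of 30 weeks and Pnliprp1 −1.04 without replicate 3. Without replicate 2 of 12 weeks H2-Oa, H2-DMb2, H2-DMa, Pecam1, Flt4 and Fabp4 had −0.25, −0.27, −0.14, −0.20, −0.12 and 0.64. Irf4 had −0.18 without replicate 2 of 30 weeks, and H2-DMb2 and Thrsp had −0.90 and 0.68 without replicate 1 of 12 weeks. Of the 8 fits that left out 1 array the call was lost in 7 for acinar genes, 5 for blood endothelium, 4 for plasma-cell and class II genes, 3 for cell-cycle genes, 1 for fat-cell and lymphatic genes and 0 for interferon genes. With slide as a block the difference rests on the 1 array of 30 weeks that shared a slide with arrays of 12 weeks. Medians were then −0.69 for interferon, −4.18 for acinar, −0.31 for lymphatic, −0.24 for plasma-cell and 0.72 for fat-cell genes. The blood endothelium (−0.024, adjusted p = 0.224), cell-cycle (−0.037, adjusted p = 0.730) and class II (−0.19, adjusted p = 0.224) lists did not pass.

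For 30 against 12 weeks limma called 143 genes, 59 higher and 84 lower, and 3877 had an unadjusted p under 0.05. The pool and the sex-linked genes differed between these ages, so that neither can be told apart from age. With slide as a fixed block 0 genes passed, and within slide 2 25 passed, of which 0 were among the 143. There replicate 1 stood alone for 30 weeks, so that the spread came from the arrays of 12 weeks alone and these 25 calls carry no spread for 30 weeks. Ratios within slide 2 were 2.18 for Rab6b, −2.49 for Gdpd3 and −1.11 for Irf7. The count was 2758 and 0 without replicates 1 and 3 of 12 weeks, 3 and 1 without replicates 1 and 3 of 30 weeks, and 1 without either array of 4 weeks.

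Between 30 and 4 weeks, ages whose sex-linked genes did not differ in the way those of 12 weeks did, the interferon list was again lower at the later age, with 6 of 18 members relatively lower (10 adjusted over the list alone) and a median of −0.50. It and 11 other lists passed with the preset correlation (adjusted p = 0.00116 to 0.0496). None of the 12 passed with an estimated correlation (adjusted p = 0.649 for interferon genes and 0.377 to 0.741 for the 12). Irf7 (−1.19 ± 0.17), Oas1a (−1.09 ± 0.20), Oas2 (−0.85 ± 0.19) and the GTPase Gbp2 (−0.54 ± 0.11) were among them. Lymphatic endothelial genes had a median of −0.65, with 6 of 12 relatively lower (7 adjusted over the list alone), among them Lyve1 (−1.95 ± 0.27), the lymphatic transcription factor Prox1 (−0.75 ± 0.15), Stab2 (−0.80 ± 0.13) and Itga2b (−0.86 ± 0.13). Reticular-cell genes had −0.37, with 8 of 18 relatively lower (8 adjusted over the list alone), such as Postn (−1.77 ± 0.12), Fn1 (−0.98 ± 0.20), Dcn (−0.97 ± 0.20) and Lum (−0.88 ± 0.15). B-cell genes had −0.41, with 4 of 15 lower (7 adjusted over the list alone), such as the co-receptor Cr2 (−0.81 ± 0.18), Bank1 (−0.92 ± 0.17) and Spib (−0.41 ± 0.11). Blood endothelium had −0.34, with 5 of 15 lower (5 adjusted over the list alone), such as Tie1 (−0.61 ± 0.09), Tek (−0.73 ± 0.16), Emcn (−0.60 ± 0.14) and Plvap (−0.52 ± 0.10).

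Class II genes had a median of −0.40 between 30 and 4 weeks, with 3 of 11 lower (4 adjusted over the list alone), H2-Ob (−1.94 ± 0.50), Cd74 (−0.66 ± 0.16) and H2-DMb1 (−0.40 ± 0.08), while H2-DMb2 (−0.99 ± 0.31) did not pass. Germinal-centre genes had −0.50, with the co-stimulator Icos (−0.53 ± 0.15) the 1 of 10 to pass (0 adjusted over the list alone), beside Fas (−0.39 ± 0.13), Gcsam (−0.51 ± 0.20) and Basp1 (−0.49 ± 0.20). Translation initiation factors had −0.12, with 11 of 38 lower and 2 higher (13 and 2 adjusted over the list alone), among them Eif1a (−1.16 ± 0.17), Eif2s1 (−1.07 ± 0.13), Eif4a2 (−0.84 ± 0.13) and Eif5b (−0.80 ± 0.11). Cytotoxic genes had 0.21 (−0.046 with arrays only centred on their median and 0.051 without replicate 1 of 4 weeks), with 3 of 14 higher (4 adjusted over the list alone), Gzma (0.96 ± 0.17), Tbx21 (0.89 ± 0.17) and Ccl5 (0.89 ± 0.26), while Klrd1 (0.78 ± 0.24) did not pass. Fat-cell genes had 0.92 with 0 of 12 passing on either count, including Plin1 (1.49 ± 0.47), Cidec (1.16 ± 0.58), Car3 (1.08 ± 0.52) and Thrsp (1.07 ± 0.46). Liver genes had 0.24, with Ahsg (1.24 ± 0.28) and Alb (1.32 ± 0.37) the 2 of 6 that were higher (2 adjusted over the list alone), beside Trf (0.32 ± 0.18) and Tat (0.15 ± 0.10), and skin genes 0.18, with Dct (3.32 ± 0.65) the 1 of 10 (1 adjusted over the list alone), beside Krt1 (0.52 ± 0.22), Lor (0.32 ± 0.12) and Krt10 (0.23 ± 0.10). Centring arrays only on their median turned Trf to −0.17 and Krt10 to −0.36. The median of all genes for this difference was then −0.26, below the cytotoxic list and Trf and above Krt10. Of the 8 fits that left out 1 array the list call was lost in 6 for liver, skin and translation genes and 5 for germinal-centre and cytotoxic genes. It was lost in 4 for blood endothelium and fat-cell genes, 3 for class II, 2 for reticular-cell, 1 for B-cell and 0 for interferon and lymphatic genes. Medians were −0.28 for germinal-centre and 0.51 for fat-cell genes without replicate 1 of 4 weeks. They were 0.36 for liver genes without replicate 2 of 4 weeks and 0.32 for skin genes without replicate 1 of 30 weeks. Without replicate 1 of 4 weeks Klrd1 had 0.30, Gcsam −0.20, Krt1 0.21, Trf 0.13, Tat 0.094, Lor 0.19, Thrsp 0.60 and Cidec 0.76.

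The single genes with the largest differences between 30 and 4 weeks were relatively lower for Gcnt1 (−4.94 ± 0.85), Erdr1 (−4.10 ± 0.43), Slpi (−2.78 ± 0.64), Adam33 (−2.50 ± 0.16), Rpgrip1 (−2.37 ± 0.35), Thumpd1 (−2.32 ± 0.51), Srsf5 (−2.32 ± 0.54), Igkv2-116 (−2.28 ± 0.29), Dpt (−2.26 ± 0.33) and Eaf2 (−2.14 ± 0.49). They were relatively higher for Dct (3.32 ± 0.65), Cd207 (2.74 ± 0.73), Tcra (2.32 ± 0.53), the proton-pump subunit Atp6v0e2 (2.14 ± 0.36), Insl6 (1.82 ± 0.15), Scg5 (1.82 ± 0.35), Gpd1 (1.81 ± 0.46), Rec114 (1.76 ± 0.34), the triglyceride-synthesis enzyme Dgat2 (1.75 ± 0.28) and Zfp862-ps (1.72 ± 0.17). Aire was relatively higher (0.63 ± 0.16, adjusted p = 0.0311), Eif4g3 relatively lower (−0.52 ± 0.12, adjusted p = 0.0179), and Deaf1 (0.27 ± 0.09, adjusted p = 0.0796) did not pass. The other probes of Thumpd1, Gpd1 and Eaf2, 1 each, had the opposite sign. Of the 55 named calls 41 were lost in at least 1 of the 8 fits that left out 1 array, Ccl5 and Spib in 6. Without replicate 1 of 4 weeks the differences were 1.89 for Dct, −1.46 for Thumpd1, 0.75 for Ahsg, 0.70 for Alb, −0.36 for Emcn and −0.30 for Icos. Without replicate 2 that of Tcra was 1.35. limma called 3470 genes, 1310 higher and 2160 lower. The count was 603 and 2001 without replicates 1 and 2 of 4 weeks and 1896 and 1571 without replicates 1 and 3 of 30 weeks. The 2 ages lay on different slides, so that slide and age cannot be told apart. Scanner, software version, the pool and its number of mice differed with them too.

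Genes near Deaf1 were compared with the rest because a targeted allele can carry neighbouring sequence of another strain. Of 325 tested genes within 20 Mb of Deaf1 on chromosome 7, 138 were called in the mean over ages, against 7907 of 17907 elsewhere (odds ratio 0.933, two-sided Fisher's exact test p = 0.573). At 12 weeks the shares were 24 of 325 and 453 of 17907 (odds ratio 3.07, Fisher's exact p = 5.34e-06), at 4 weeks the odds ratio was 0.967 (Fisher's exact p = 0.841) and at 30 weeks 1.00 (Fisher's exact p = 1). Within 10 and 5 Mb the odds ratios in the mean were 0.676 and 0.610 (Fisher's exact p = 0.0165 and 0.00689). Genes are not independent units in this test.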

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

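The tests of dye, slide, pool, carried-over tissue and neighbouring sequence in this part were chosen after the results they address had been seen, and the counts over other splits of the arrays were planned.

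Interferon-response genes were lower in knockout nodes at 30 weeks, and the difference from 12 weeks (list median −0.65) and from 4 weeks (−0.50) passed the preset-correlation test and not the one with an estimated correlation. A dye bias of these probes that is equal on all arrays is argued against, since the lowest list median of the 4- and 12-week arrays lay 0.43 above the highest of 30 weeks. A difference between slides cannot be told apart, because the median with slide as a block, −0.69, rests on the 1 array of 30 weeks that shared a slide with 12 weeks. The pool of 30 weeks stays open as well: the wild-type channels of its arrays correlated at no less than 0.998, so a pool with unusually high interferon genes would lower the ratio of all 3 arrays alike. The sex-linked genes also differed between 12 and 30 weeks, which the difference from 12 weeks cannot be told apart from. Of the 12-week list medians (0.060, 0.46 and −0.076 in replicates 1, 2 and 3), the highest was that of replicate 2, whose sex-linked genes differed from its pool. Irf7, a member of the list, lies close to Deaf1, and an effect of neighbouring sequence on it was not tested. An effect of age on the knockout is the biological explanation that the design names, and it was not tested apart from the pool.

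Acinar transcripts lay far from 0 on all 3 arrays of 30 weeks, at list medians of −4.09, 3.98 and −4.50, and their difference from 12 weeks had a median of −1.72. A loss of these transcripts set by the knockout was not seen in replicate 2, whose median was 3.98 with an SD of 0.60 between members. Replicates 1 and 3 go with a loss. Since the contrary value comes from 1 array, into which tissue may have been carried, a loss cannot be excluded. Pancreatic tissue taken along with the node in varying amounts is a candidate explanation that was not told apart from the knockout. On each array 100% of the 25 members lay on the side of the list median, including abundant enzymes such as Amy2a5 and Cela1. With medians this far from 0 that share follows, and a loss set by the knockout would give it too. The log2 level of the list was 13.6 to 15.1 in the wild-type channel of these arrays. In the knockout channel it was 10.8, 17.5 and 10.4 in replicates 1, 2 and 3. The pool thus held these transcripts too, and its level enters all 3 ratios. Whether tissue was carried into the pool was not tested. Islet genes, of which 9 were measured, had medians of 0.15, 0.21 and 0.09 on these arrays. No biological explanation other than the knockout was tested.

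Among the 17 genes with an absolute log2 ratio over 1 in the mean over ages, 2 lay within 20 Mb of Deaf1, Gdpd3 and Tmem80 (odds ratio 7.38, Fisher's exact p = 0.0361), and within 5 Mb only Tmem80 (odds ratio 8.43, Fisher's exact p = 0.119). Sequence around Deaf1 that came with the targeted allele may contribute, but this cannot be told apart from effects of the knockout. The values differ between ages: for ratios of this size the odds ratio was 10.6 at 12 weeks (Fisher's exact p = 0.000933; within 5 Mb 5.62, Fisher's exact p = 0.170), 1.11 at 4 weeks and 1.72 at 30 weeks, and for all called genes it was 0.933 in the mean and 3.07 at 12 weeks (Fisher's exact p = 5.34e-06). Further genes with ratios of this size within 20 Mb included Cpxm2 at 12 weeks and Irf7 at 30 weeks, Irf7 also within 5 Mb. For Gdpd3 the difference between 30 and 12 weeks was −2.56, which a probe mismatch changing the measured ratio by 1 factor at every age would not give. The gene dropped out under the stricter filter on dim probes, and a mismatch whose effect varies with a dim signal was not tested. A mismatch is thus not excluded for Gdpd3. For Tmem80 the same difference was 0.073, and a mismatch cannot be told apart from lower expression. Genotypes of the mice around the gene were not used here.

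Differences of the knockout effect between ages were picked out because the difference itself was tested. Between 12 and 4 weeks 1284 genes passed, between 30 and 12 weeks 143 and between 30 and 4 weeks 3470. Of the 10 ways to split the 6 arrays of 12 and 30 weeks into groups of 3, only the real one gave as many as 143 genes and the highest other count was 0. These 10 splits are too few for a share under 0.05.

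Among the named genes, those called in opposite directions at the 2 ages compared are given here. From 4 to 12 weeks they were Aqr (difference 1.49), Rmrp (1.36), Tatdn2 (1.3) and Ptn (−1.46). From 12 to 30 weeks they were Fhl1 (1.03), Aire (0.89), Plac9a (−1.07), Adam33 (−1.24) and Tatdn2 (−1.25). For Aire the call at 12 weeks was lost in each of the 8 fits that left out 1 array, and the call of the difference in 7 of them. From 4 to 30 weeks they were Atp6v0e2 (2.14), Insl6 (1.82), Zfp862-ps (1.72), Tbx21 (0.89), Stab2 (−0.80), Eif4a2 (−0.84), Eif2s1 (−1.07), Eif1a (−1.16), Igkv2-116 (−2.28), Adam33 (−2.50) and Erdr1 (−4.10). Leaving out 1 array in turn, every named call of a difference between 12 and 4 weeks was lost in at least 1 fit. Between 30 and 12 weeks every named call was lost in at least 3 fits. Of the 55 between 30 and 4 weeks, 41 were lost in at least 1.

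Lists whose shift differed between 12 and 4 weeks were reticular cells (median −0.38) and cell cycle (0.25). Between 30 and 12 weeks they were, besides interferon and acinar genes, lymphatic endothelium (−0.27), blood endothelium (−0.16), plasma cells (−0.17), fat cells (0.98), cell cycle (−0.15) and class II (−0.23). Between 30 and 4 weeks they were, besides interferon genes, liver (0.24), skin (0.18), reticular cells (−0.37), lymphatic endothelium (−0.65), blood endothelium (−0.34), B cells (−0.41), germinal centre (−0.50), cytotoxic cells (0.21), fat cells (0.92), translation initiation (−0.12) and class II (−0.40). None of these passed with an estimated correlation.

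The second Deaf1 probe, which entered only the setting that took the mean of all probes of a gene, read 3.11 on replicate 2 of 30 weeks against −0.74 and −0.62 on the other arrays of that age. Acinar genes had medians of the same sign on these arrays, 3.98 in replicate 2 and −4.09 and −4.50 in replicates 1 and 3. A link between the probe and acinar transcripts was not tested.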

How the results depend on the processing

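The corrections for GC content, the mean of 12 and 30 weeks only and slide 2 alone were chosen after the data were seen; the other settings were planned. Of 254 results for named genes other than Deaf1 195 were called. Of these 189 kept their direction and 54 also their call under every setting, and none of the 27 list shifts changed the direction of its test. The count at 30 weeks moved by over 1.5 times only with the fold minimum and with replicate 1 or 3 of that age left out (4114 and 3929). The cause of the changes below was not tested except where a setting tests fewer arrays or adds a fold minimum. The lower share of probes well above background at 4 weeks (37.2% in the wild-type channel of replicate 2) limits what those arrays measure.

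Median centring without loess called 9740, 10280 and 12164 genes at 4 and 12 weeks and in the mean, 51 and 7 between 12 and 4 and between 30 and 12 weeks, and 66 list shifts. It moved the median ratio of all genes to 0.49, 0.41 and 0.15 at the 3 ages and 0.34 in the mean, and raised the share of calls that were higher from 67.5%, 47.5%, 52.9% and 57.7% to 96.1%, 94.1%, 88.0% and 91.1%. For the differences 12 minus 4, 30 minus 12 and 30 minus 4 weeks, where the median of all genes became −0.10, −0.14 and −0.26, that share fell from 19.7%, 41.3% and 37.8% to 3.92%, 0% and 5.50%. Deaf1 turned to 0.39 at 4 weeks and −0.11 for 30 minus 4 weeks, passed in the mean (0.50) and not for 12 minus 4 weeks (0.43). Aire turned to 0.38, 0.027 and 0.35 at 4 and 12 weeks and in the mean, Tbx21 and Ccl5 at 4 weeks to 0.38 and 0.21, H2-Eb1 at 30 weeks to 0.041, and Trf and Krt10 for 30 minus 4 weeks to −0.17 and −0.36. Relative to the shift of all genes, Aire in the mean and Krt10 turned and the others did not. The medians of the cytotoxic list at 4 weeks (0.23) and for 30 minus 4 weeks (−0.046) and of class II at 30 weeks (0.042) turned too, while their tests against the other genes kept their direction and did not pass.

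The scanner's log ratio and the series matrix gave 6398 and 6483 genes at 4 weeks, 172 and 179 at 12 weeks, 2149 and 2195 for 12 minus 4 weeks, 5 and 2 for 30 minus 12 weeks and 10 and 9 list shifts. Calls that were higher made up 56.1% and 55.5% at 4 weeks, 60.5% and 60.3% at 12 weeks, 37.4% and 38.4% for 12 minus 4 weeks and 80% and 100% for 30 minus 12 weeks. Under both Deaf1 at 12 weeks (0.41) did not pass and Aire turned to 0.032 for 12 minus 4 weeks. Scaling between arrays gave 1961 genes at 12 weeks and 61 for 30 minus 12 weeks (27.9% higher), where Eif4g3 turned to 0.15.

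Arrays of equal replicate number had correlations of their deviations from the age mean of 0.048 and −0.077 between 4 and 12 weeks, −0.029, 0.0031 and 0.021 between 12 and 30 weeks and 0.24 and 0.17 between 4 and 30 weeks. A replicate block left 2752, 294, 354, 0 and 2132 genes at 4 weeks, 12 weeks, 12 minus 4, 30 minus 12 and 30 minus 4 weeks, and with the GC correction 2095, 52, 260, 0 and 2155. Deaf1 then did not pass at 12 weeks (0.34 and 0.41) or for 12 minus 4 weeks (0.50 and 0.44), and with the GC correction added it passed in the mean (0.20). Slide as a random block, with a consensus correlation of −0.26, gave 6607, 8971, 4483, 2325 and 6017 genes in the same contrasts, and Deaf1 passed at 4 weeks (−0.17), in the mean (0.091), for 30 minus 12 (−0.26) and for 30 minus 4 weeks (0.26). For 30 minus 12 weeks a fixed slide block left 0 genes and slide 2 alone 25.

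A fit on the ages compared alone gave 6, 178 and 1 genes at 12 weeks, for 12 minus 4 and for 30 minus 12 weeks, without a call for Deaf1 at 12 weeks (0.34) or for 12 minus 4 weeks (0.51). A trended robust prior gave 10 genes at 12 weeks (Deaf1 0.34, not passing). The mean of all probes that passed the filter gave 313 genes at 12 weeks and 787 for 12 minus 4 weeks, and Deaf1 did not pass in either (0.24 and 0.43) and turned to 0.10 for 30 minus 12 weeks. Array weights gave 3185 genes for 30 minus 12 weeks and 14 list shifts, with Deaf1 passing at 30 weeks (0.12) and for 30 minus 4 weeks (0.29). The GC correction gave 16 list shifts and Deaf1 passed at 30 weeks (0.22) and in the mean (0.20), as it did in the mean without background correction (0.11). List shifts numbered 45 without the filter on dim probes, 14 with the strict one, under which Thumpd1 turned to −0.034 at 4 weeks and 0.64 for 30 minus 4 weeks, and 0 with an estimated correlation (27 in the fit reported). An absolute log2 ratio over 1 left 257, 26, 170, 17, 141, 31 and 471 genes in the 7 contrasts. The odds ratio near Deaf1 turned from 0.933 in the mean to 3.07 at 12 weeks and 1.00 at 30 weeks, and passed within 10 Mb (0.676) and 5 Mb (0.610).

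Leaving out each array in turn gave 494 to 5166 genes at 4 weeks, 18 to 1862 at 12 weeks, 3929 to 7941 at 30 weeks, 5114 to 8720 in the mean, 1 to 1772 for 12 minus 4, 0 to 2758 for 30 minus 12 and 603 to 4577 for 30 minus 4 weeks, with the lows without replicate 1 of 4 weeks (4 weeks, mean, 12 minus 4 and 30 minus 4 weeks), 1 or 3 of 12 weeks (12 weeks and 30 minus 12 weeks) and 3 of 30 weeks (30 weeks), the highs without replicate 1 of 12 weeks (4 weeks, 30 minus 12 and 30 minus 4 weeks) or 2 of 12 weeks (the others), and 15 (without replicate 1 of 12 weeks) to 39 list shifts. With 1 array of 4 weeks left out, the other is assumed to vary like the arrays of the other ages. Deaf1 ran from 0.33 to 0.35 at 12 weeks and from 0.46 to 0.55 for 12 minus 4 weeks, and these calls were lost in 4 and 3 of the 8 fits.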

Other observations

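At 12 weeks several immediate-early and heat-shock genes and 3 chemokines differed in their ratios between replicates. That these arrays share their pool is an assumption. The heat-shock gene Hspa1a had log2 ratios of 2.70, −5.26 and 2.83 in replicates 1, 2 and 3, Dnajb1 2.09, −2.31 and 2.43, the immediate-early genes Fos 1.06, −2.16 and 1.71 and Egr1 1.34, −1.91 and 1.80, and the monocyte chemokines Ccl2 2.33, −2.47 and 2.30 and Ccl7 2.96, −1.87 and 2.70. The neutrophil chemokine Cxcl1 had 2.27, −1.13 and 3.02, while the list of inflammatory cytokines and chemokines had medians of 0.40, −0.23 and 0.15. List medians of the immediate-early and heat-shock genes were 1.29, −1.0 and 1.64 at this age and lay between −0.21 and 0.12 at the others. Neutrophil genes had medians of −0.29, −1.96 and 0.23, with S100a9 at −0.53, −2.94 and 0.83. Replicate 2 is the array whose sex-linked genes differ from the pool (Xist 5.32, Kdm5d −1.86), the difference between replicates was not tested, and these genes were chosen after their values were seen.

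Lists that did not shift in any comparison are given by their median in the mean over ages and the lowest adjusted p of limma's camera over the 7 comparisons. By limma's camera they were islet (0.09, adjusted p = 0.220), gut (−0.04, adjusted p = 0.622), neural (0.08, adjusted p = 0.219) and reproductive or endocrine antigens (−0.04, adjusted p = 0.139), T cells (−0.10, adjusted p = 0.138), regulatory T cells (0.03, adjusted p = 0.116), dendritic cells (−0.04, adjusted p = 0.0570), macrophages (−0.04, adjusted p = 0.0590), neutrophils (−0.11, adjusted p = 0.0788), erythroid cells (−0.26, adjusted p = 0.182), skeletal muscle (−0.11, adjusted p = 0.157), inflammatory cytokines and chemokines (0.20, adjusted p = 0.370) and immediate-early and heat-shock genes (0.15, adjusted p = 0.0739). Of the islet list 9 of 24 genes were measured. The sex-linked list, with 4 measured genes, was not tested.

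On all 8 arrays the log2 ratio fell with the GC content of the probe, with a Spearman correlation across genes of −0.39 to −0.15, where genes are not independent replicates. In the mean over ages the probes of genes called higher held 39.1% GC, those called lower 47.0% and the others 43.4%. For 12 minus 4 weeks these shares were 45.0%, 40.4% and 43.1%. They were 38.7%, 45.5% and 43.0% for 30 minus 12 weeks and 42.7%, 42.2% and 43.1% for 30 minus 4 weeks. The trend was unequal between arrays, so it need not cancel in the differences between ages. After a correction for this trend, chosen after it was seen, 7491 genes passed in the mean, 3795 higher and 3696 lower, and 3675, 417 and 6943 at 4, 12 and 30 weeks. These were partly other genes. Of the genes called without the correction, 5880 of 8109 remained called in the mean. At 4, 12 and 30 weeks 3163 of 4168, 344 of 480 and 5639 of 7176 remained.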
